A study of Homo sapiens with 8 samples.

How the data were processed

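Poly(A)-selected mRNA of the human esophageal squamous cell carcinoma line KYSE150 was sequenced in 8 libraries, 2 in each of 4 groups. The groups were normoxia, hypoxia, hypoxia with sodium oxamate, and hypoxia with sodium oxamate and sodium lactate. The last column names carry an abbreviation that was read as sodium lactate from the treatment protocol in the labels. Doses, durations and oxygen levels are not given in the sources used here. Cells were grown in RPMI-1640 medium with fetal bovine serum.

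The authors deposited one table of raw counts per gene, and the values are whole numbers in every cell without normalization. FastQC 0.11.9, STAR 2.7.8a and RSEM 1.3.3 and the builds hg38 and GRCh38 are listed by the authors with no role given. The counts may be RSEM estimates that were rounded before deposit. Strandedness, annotation release and filters are not given in the sources used here. The table lists 61517 genes, of which 46 are second copies of pseudoautosomal genes with 0 counts. Total counts were 23390612 and 27503041 in normoxia, 26922656 and 25861332 in hypoxia, 29406061 and 28125223 with oxamate and 21845676 and 27236915 with lactate added. A floor of 3 counts corresponds to 0.102 to 0.137 CPM of these totals. Biotypes and positions were taken from GENCODE release 29, which holds 98.0% of the tested gene identifiers.

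Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with a minimum count of 10 over the 4 groups, which left 15554. Libraries were scaled by TMM, with factors of 1.15 in both normoxia libraries, 1.10 in hypoxia, 0.879 with oxamate and 0.901 with lactate added. One quasi-likelihood model with robust dispersion was fitted to all 8 libraries with 4 group means and 4 residual degrees of freedom. Each of 4 comparisons was tested with the two-sided quasi-likelihood F test of edgeR. P-values were adjusted by Benjamini-Hochberg over all tested genes, and a gene passed at an adjusted p under 0.05. The standard error of a log2 fold change was derived from the F statistic. Expression per group is the mean and SD of TMM-scaled CPM. For genes with few counts, ratios of scaled counts carry 95% binomial (Clopper-Pearson) counting intervals.

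A total of 31 gene lists were written before the data were examined, holding 880 genes that all matched the table. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and adjusted over the 29 lists in each comparison. Lists of leukocyte markers and of fibroblast and endothelial markers had 4 tested members each and are given as summed CPM of the library totals. Camera with an estimated correlation and fry were run beside it, and fry tests only whether the genes of a list move one way on balance. For each list, counts of passing members were taken both over all genes and adjusted over the list alone. These agreed for all called lists except the hypoxia and HIF targets in hypoxia against normoxia. The overlap of comparisons that share a group was set against independent lists of the same sizes, and against 20 simulations without any effect. Covariances were also computed on log2 CPM with a prior count of 2, giving each effect a different library of the shared group.

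Named genes followed a rule fixed before the data were examined. It took 9 genes of lactate metabolism, the HIF-1 complex and its targets, and CD274 in every comparison. In the first 3 comparisons it took the 5 largest increases and the 5 largest decreases among passing genes with a mean log2 CPM of at least 1, replicates that did not overlap and a symbol that was not clone-based. It added 2 members of each of up to 6 called lists by smallest p in the direction of the list. For the patterns over 3 comparisons it took the 4 genes with the smallest adjusted p in each direction, of which 1 is not reported here. Genes named outside this rule (MT-CO1, MT-ND4, MT-ND6, PVR and VTCN1 in hypoxia against normoxia, and the keratin, metalloproteinase and stress genes of the closing section) were chosen after their values were seen. Of 66 named genes with coordinates, 38 share exon bases with another gene, and for 14 of them a partner reached at least 10% of the level of the gene, both averaged over all libraries.

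Alternatives were RLE size factors, upper quartile normalization, no low-count filter, a stricter filter of 50 counts in 2 libraries, DESeq2 1.42.0, a test against a fold change of 1.5, the replicate number as a block, a fit of the 2 compared groups alone and leaving out each library in turn. Permuted groupings were not run because each group has 2 libraries. The method was tested on simulated data with 200 changed genes. There edgeR recovered between 56.7% and 64.2% of 1.5-fold, between 73.1% and 77.6% of 2-fold and between 89.4% and 93.9% of 4-fold changes. Between 11 and 18 of 176 to 190 calls were false, more than the 5% aimed at in each of the first 3 comparisons. The last comparison was not simulated. In the data, between 64.9% and 80.5% of tested genes were called. The simulation therefore does not cover scaling or false calls where most genes change. Figures were drawn with matplotlib 3.10.9.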

Results

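Poly(A)-selected RNA of KYSE150, a human esophageal squamous cell carcinoma cell line, was sequenced from 4 groups of 2 libraries. One group was kept in normoxia and another in hypoxia. The third was kept in hypoxia with sodium oxamate, an inhibitor of lactate dehydrogenase. The fourth received sodium lactate together with oxamate in hypoxia. Oxygen levels, doses and durations are not given in the sources used here. The series title places the experiment in a study of HIF-1α lactylation and immune evasion in hypoxia. Total counts per library ran from 21845676 to 29406061, and 15554 of 61517 listed genes passed the expression filter. The first 3 principal components carried 50.5%, 25.4% and 15.8% of the variance and set the 4 groups apart. Replicates differed by more than sampling noise, with a chi-square per degree of freedom between 1.85 and 4.83. Values below are fitted log2 fold changes ± standard error, or TMM-scaled CPM as mean ± SD (n = 2 libraries per group). The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The common biological coefficient of variation was 3.06%, and changes well under 2-fold passed the test. A count of 0 in both libraries of a group is read against a floor of 3 counts over the group. Intervals and floors cover counting error only. The rule for naming genes was fixed before the data were examined and asks for a minimum level of expression.

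Positions of the 9 genes chosen in advance on GRCh38 are those of GENCODE release 29. The annotation placed LDHA (ENSG00000134333) at chromosome 11 from 18394388 to 18408425 and LDHB (ENSG00000111716) at chromosome 12 from 21635342 to 21757857. It placed HIF1A (ENSG00000100644) at chromosome 14 from 61695513 to 61748259, ARNT (ENSG00000143437) at chromosome 1 from 150809705 to 150876768 and EP300 (ENSG00000100393) at chromosome 22 from 41091786 to 41180079. It put CD274 (ENSG00000120217) at chromosome 9 from 5450503 to 5470566, VEGFA (ENSG00000112715) at chromosome 6 from 43770184 to 43786487, CA9 (ENSG00000107159) at chromosome 9 from 35673856 to 35681159 and SLC2A1 (ENSG00000117394) at chromosome 1 from 42925375 to 42959176.

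The first comparison asked which transcripts differed between cells in hypoxia and in normoxia, both without drug. Genes of glucose uptake, glycolysis and the response to low oxygen were higher in hypoxia. LDHA, which encodes the lactate dehydrogenase subunit that favours lactate formation, rose from 1327 ± 6.05 to 5657 ± 0.844 CPM (log2 fold change 2.09 ± 0.027, n = 2 per group). CA9, encoding carbonic anhydrase IX, rose from 6.36 ± 0.889 to 245 ± 3.75 CPM (5.26 ± 0.071). CD274, which encodes the immune checkpoint ligand PD-L1, went the other way and fell from 20.1 ± 0.157 to 14.3 ± 0.0699 CPM (-0.49 ± 0.075, adjusted p = 4.67e-06). Of the other genes chosen in advance, SLC2A1, encoding the glucose transporter GLUT1, rose by 1.76 ± 0.033, and VEGFA, encoding an angiogenic growth factor, by 1.83 ± 0.056. ARNT, the partner of HIF-1α in the HIF-1 dimer, rose by 0.64 ± 0.066. EP300, an acetyltransferase and HIF coactivator, changed by -0.48 ± 0.063. HIF1A did not pass (0.05 ± 0.037, adjusted p = 0.218), but passed as higher with upper quartile normalization (0.16) and with the stricter count filter (0.10). LDHB, the subunit that favours pyruvate formation, passed with a log2 fold change of -0.12 ± 0.031, and no longer passed with upper quartile normalization (-0.01).

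**Figure D1:**
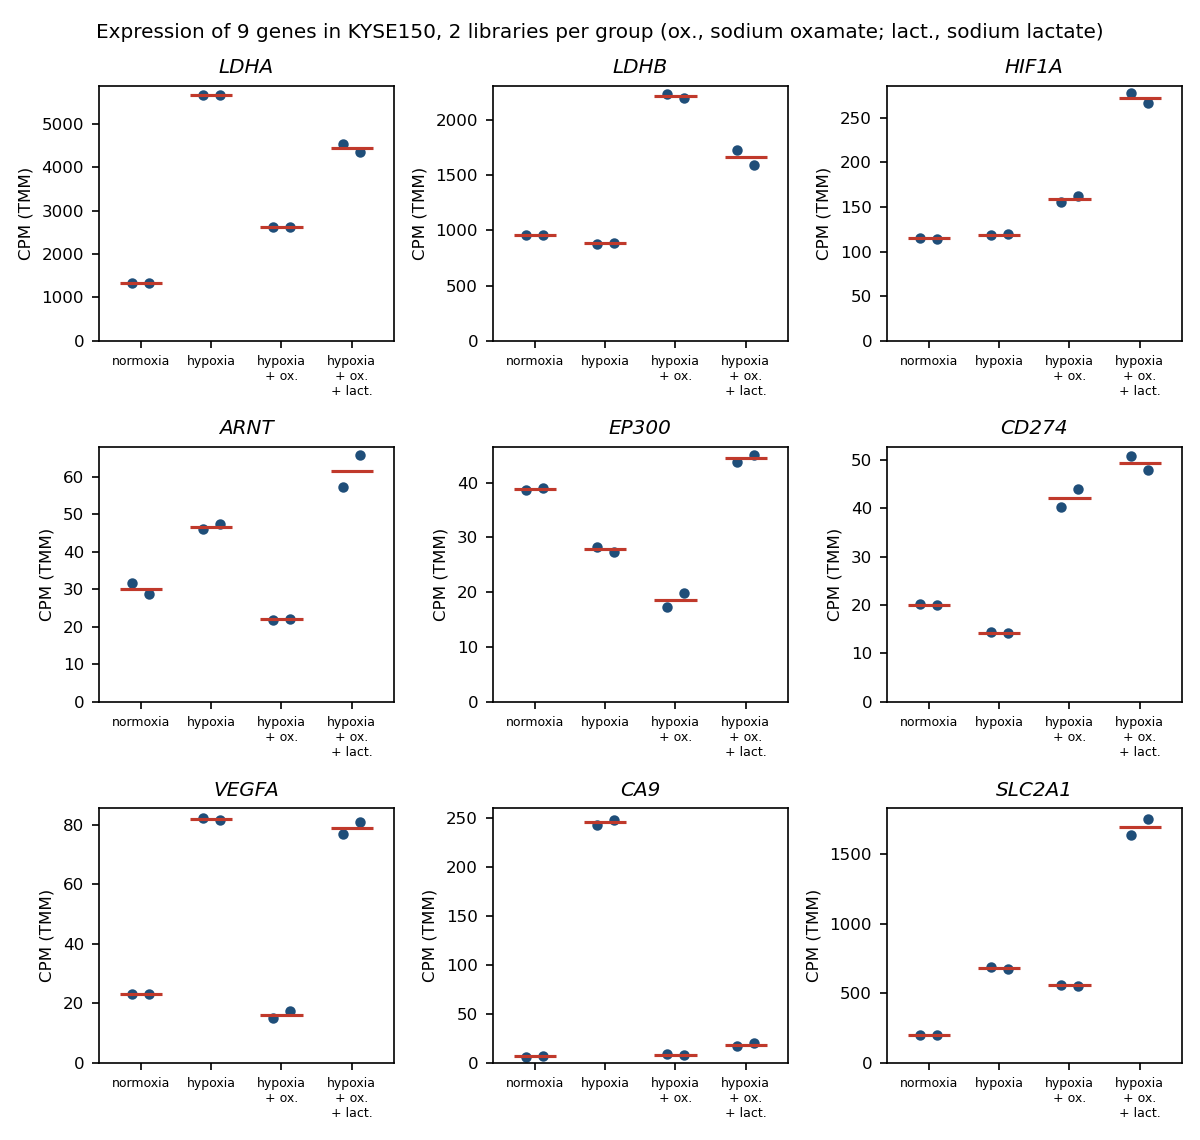
Expression of 9 genes chosen in advance, as TMM-scaled CPM on linear axes that start at 0. Points are single libraries and red lines the mean of the 2 libraries of a group, with CA9 at 245 CPM in hypoxia and at 8.06 CPM with oxamate, while CD274 was at 14.3 CPM in hypoxia and at 42.2 CPM with oxamate.

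Of the 38 tested hypoxia and HIF target genes outside glycolysis, 35 rose in hypoxia and none fell (36 adjusted over the list alone), with a median log2 fold change of 2.60. DDIT4, an mTORC1 inhibitor, rose by 4.81 ± 0.039, and HILPDA, a lipid droplet protein gene, by 5.14 ± 0.048. All 23 genes of glycolysis and of glucose and lactate transport rose (median 1.94), among them SLC2A3, encoding the glucose transporter GLUT3, by 5.78 ± 0.040, and HK2, encoding hexokinase 2, by 3.52 ± 0.030. In the opposite direction, 31 of 32 nucleolar ribosome biogenesis genes fell and 1 rose (median -1.80). In that list, RRS1 changed by -3.88 ± 0.063 and NOLC1 by -1.91 ± 0.035. Of 19 heat shock and cytosolic chaperone genes, 17 fell and 2 rose (median -0.96), including HSPA8 (-3.15 ± 0.029) and HSPH1 (-2.24 ± 0.035). HSPA1A and HSPA1B of that list are near-identical copies and uncertain. Of 44 DNA replication and S phase genes, 39 fell and 4 rose (median -0.93), including the replication factor genes MCM10 (-2.23 ± 0.049) and FEN1 (-1.86 ± 0.042). These 5 lists passed the camera test with the preset and with an estimated correlation, where their adjusted p lay between 0.00478 and 0.0105.

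The remaining 9 lists called in this comparison lost the call with an estimated correlation. Of the 13 protein-coding genes on the mitochondrial chromosome, 10 fell and 3 rose (adjusted p = 0.0675 with an estimated correlation). MT-CO3 changed by -2.31 ± 0.027 and MT-ATP6 by -2.10 ± 0.031, while MT-CO1 and MT-ND4 were higher by 0.08 ± 0.026 and 0.13 ± 0.028. Of 51 cytosolic ribosomal protein genes, 50 rose and none fell, with a median of 0.42 (adjusted p = 0.134 with an estimated correlation). Of 5 tested metallothionein genes, 4 rose (median 2.22, or 2.11 with MT1B, at 0 in normoxia, set at its bound, adjusted p = 0.0675 with an estimated correlation). Of 17 replication-dependent histone genes, whose mRNAs mostly lack poly(A), 13 rose and none fell (median 2.07, adjusted p = 0.0675 with an estimated correlation). Endoplasmic reticulum chaperone genes fell as a list, with 13 lower and 5 higher of 23 (adjusted p = 0.0532 with an estimated correlation). Of 25 squamous and keratinocyte genes, 14 rose and 8 fell (adjusted p = 0.0675 with an estimated correlation). Cholesterol biosynthesis genes, with 15 of 22 higher and 5 lower, had an adjusted p = 0.0765 with an estimated correlation. NF-kB response genes, with 11 of 19 higher and 7 lower, had an adjusted p = 0.0807 with an estimated correlation, and genes of fatty acid synthesis, with 13 of 24 higher and 10 lower, had an adjusted p = 0.195 with an estimated correlation. Without a low-count filter the squamous, NF-kB and fatty acid lists also lost their call, with medians of 0.0070, 0.40 and 0.28. Among 16 immune checkpoint and immunosuppressive surface genes, 9 rose and 5 fell, and the list was not called (camera adjusted p = 0.098). Its members went both ways, with VTCN1, encoding the checkpoint ligand B7-H4, higher by 5.39 ± 0.26 and PVR lower at -1.14 ± 0.04.

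By size of change, NDRG1, a gene of the response to low oxygen, rose from 36.3 ± 5.18 to 7356 ± 36.2 CPM, a fitted 201-fold difference. CASP14, encoding a caspase of keratinocyte differentiation, had 605 counts in hypoxia against 6 in normoxia, a ratio of 102 (95% counting interval 46.6 to 279). DEPP1 and ANKRD37 rose by 6.23 ± 0.109 and 6.10 ± 0.111, although ANKRD37 shares 35.2% of its exon bases with UFSP2 on the opposite strand, which was at 10.8 and 9.55 CPM in normoxia, above ANKRD37. BHLHE40-AS1, antisense to BHLHE40, had 253 counts against 4, a ratio of 63.9 (interval 24.7 to 236), and is uncertain because strand was not stated. Among genes open to the naming rule, the 5 largest decreases were in FAM222A (-4.38 ± 0.276), FAM86C1P (-4.22 ± 0.166), DKK1 (-4.20 ± 0.059), KBTBD8 (-4.17 ± 0.330) and AEN (-4.15 ± 0.093). DKK1 encodes a WNT antagonist and AEN a p53-induced nuclease, while FAM86C1P belongs to a family of similar copies and is uncertain. edgeR called 5702 genes higher and 5727 lower at an adjusted p under 0.05, of which 2427 and 2033 differed at least 2-fold. The share of counts from the mitochondrial chromosome was 5.74% and 5.73% in normoxia and 4.78% and 4.61% in hypoxia, and that from mitochondrial ribosomal RNA went from 0.620% and 0.615% to 1.34% and 1.31%. The share of lincRNA and antisense genes was 0.646% and 0.651% in normoxia and 0.907% and 0.906% in hypoxia. Summed leukocyte markers were at 42.5 and 47.2 CPM of the library totals in normoxia and at 134 and 127 CPM in hypoxia. With oxamate they were at 79.4 and 78.5 CPM and with lactate added at 92.4 and 95.4 CPM. Among them CD68, a lysosomal gene, reached 116 CPM in its highest library. That value is TMM-scaled and cannot be subtracted from the sums. Fibroblast and endothelial markers summed to 5.39 and 5.02 CPM in normoxia, 15.93 and 15.97 CPM in hypoxia, 2.65 and 3.31 CPM with oxamate and 2.79 and 2.94 CPM with lactate added.

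The second comparison asked what oxamate changed in hypoxic cells. Many genes that were higher in hypoxia were lower with oxamate, and genes of ribosome biogenesis were higher. CA9 fell from 245 ± 3.75 to 8.06 ± 0.924 CPM (-4.93 ± 0.070, n = 2 per group) and VEGFA from 82.0 ± 0.520 to 16.2 ± 1.51 CPM (-2.34 ± 0.061). LDHA changed by -1.11 ± 0.026 and LDHB by 1.33 ± 0.032. CD274 rose from 14.3 ± 0.0699 to 42.2 ± 2.63 CPM (1.56 ± 0.069, adjusted p = 3.19e-15). HIF1A rose by 0.42 ± 0.037, while its partner ARNT (-1.09 ± 0.071) and the coactivator EP300 (-0.59 ± 0.072) fell. SLC2A1 changed by -0.29 ± 0.031. CA9 shares 38.5% of its exon bases with ARHGEF39, which was at 14.6 and 14.3 CPM in normoxia, above CA9, at 22.8 and 21.6 CPM in hypoxia, at 4.22 and 4.21 CPM with oxamate and at 3.61 and 2.73 CPM with lactate added. The low levels of CA9 are uncertain because strand was not stated.

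Of 38 hypoxia and HIF target genes, 33 fell with oxamate and 4 rose (median -2.29), including HILPDA (-5.17 ± 0.049) and DDIT4 (-2.91 ± 0.035). Of 23 genes of glycolysis and glucose and lactate transport, 19 fell and 4 rose (median -0.71), including SLC2A3 (-3.96 ± 0.035) and ENO2, encoding an enolase (-3.86 ± 0.044). All 32 nucleolar ribosome biogenesis genes rose (median 1.94), including NOP16 (2.57 ± 0.038) and RRP12 (2.89 ± 0.043). Among 51 cytosolic ribosomal protein genes, 50 rose and 1 fell (median 0.90), including RPL18 (1.26 ± 0.028) and RPL8 (1.03 ± 0.025). Heat shock and cytosolic chaperone genes rose in 15 of 19 cases and fell in 2 (median 1.39), including HSPA8 (3.05 ± 0.028) and HSPH1 (2.74 ± 0.035). Of 58 nuclear genes of the respiratory chain, 54 rose and 2 fell (median 0.72), and of 25 genes of the TCA cycle and pyruvate entry, 20 rose and 3 fell (median 0.81). Of 44 S phase genes, 34 rose and 6 fell (median 0.94). All 5 metallothionein genes rose (median 1.98), and 17 of 23 endoplasmic reticulum chaperone genes rose while 5 fell (median 0.69). These 10 lists were called by camera with the preset correlation and with an estimated one, where their adjusted p lay between 0.017 and 0.0421.

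All 13 mitochondrial genes fell (median -1.23, adjusted p = 0.105 with an estimated correlation), including MT-ATP6 (-2.35 ± 0.033) and MT-ATP8 (-3.42 ± 0.059), which overlap. NRF2 antioxidant genes, with 14 of 23 higher and 4 lower, had an adjusted p = 0.0643 with an estimated correlation. Cholesterol biosynthesis genes, with 14 of 22 lower and 5 higher, had a median of -0.46 and an adjusted p = 0.133 with an estimated correlation. The cholesterol call also ended without hypoxia replicate 1 or 2 (median -0.33 and -0.36), without oxamate replicate 1 or 2 (-0.28 and -0.21), with RLE size factors (-0.37), with the stricter count filter (-0.42) and in a fit of the 2 groups alone (-0.35). Of the 16 immune checkpoint and immunosuppressive surface genes, 10 fell and 4 rose, and the list was not called (adjusted p = 0.745). VTCN1 had 673 counts in hypoxia against 7 with oxamate, a ratio of 83.9 (interval 40.5 to 210). The MHC class I list, with 11 of 20 higher and 6 lower, and the interferon-stimulated genes, with 10 of 30 higher and 14 lower, were not called (adjusted p = 0.12 and 0.334).

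GADD45A, a growth arrest and stress gene, rose from 27.1 ± 0.260 to 700 ± 16.7 CPM (4.69 ± 0.041). MMP3, encoding the matrix metalloproteinase stromelysin-1, rose by 5.24 ± 0.235 and the phosphatase gene DUSP8 by 4.66 ± 0.274. THBS1-IT1 (4.94 ± 0.249) lies within THBS1 and is uncertain. F8A2 had 0 counts in hypoxia and 303 with oxamate. Read against the floor of 3 counts over the group, F8A2 was 116-fold higher, and the interval of its ratio began lower, at 93.5. F8A2 is uncertain because near-identical copies may share its reads. Large decreases were also found in DEPP1 (-6.64 ± 0.118) and KCTD11 (-6.53 ± 0.063). CSPG4 had 474 counts in hypoxia against 5 with oxamate, a ratio of 82.8 (interval 35.2 to 256). Among genes open to the naming rule, the largest fitted decrease was that of the pseudogene SDAD1P1, which had 376 counts against 1, a ratio of 328 (interval 58.6 to 12999), and is uncertain because its parent gene shares its sequence. SDAD1P1 also shares 1.4% of its exon bases with BNIP3L on the opposite strand, and strand was not stated. BNIP3L was at 9701% of its level, averaged over all libraries, and changed by -3.41 with oxamate. edgeR called 5560 genes higher and 6965 lower, of which 2226 and 4274 differed at least 2-fold. The excess of lower genes depended on the processing. It was smaller with the stricter count filter (5349 higher and 5605 lower), DESeq2 (5502 and 5885) and RLE size factors (5922 and 6593). It was larger with upper quartile normalization (5273 and 7311) and without a low-count filter (5501 and 7444). The median log2 fold change of all genes was -0.20. The mitochondrial share of counts was 2.45% and 2.44% with oxamate, against 4.78% and 4.61% in hypoxia, and the share of lincRNA and antisense genes went from 0.907% and 0.906% in hypoxia to 0.478% and 0.475%. Mitochondrial ribosomal RNA went from 1.34% and 1.31% to 0.964% and 0.966%. Of 17 replication-dependent histone genes, 9 were lower and 3 higher (median -1.04), and the list was not called (adjusted p = 0.167).

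**Figure D2:**
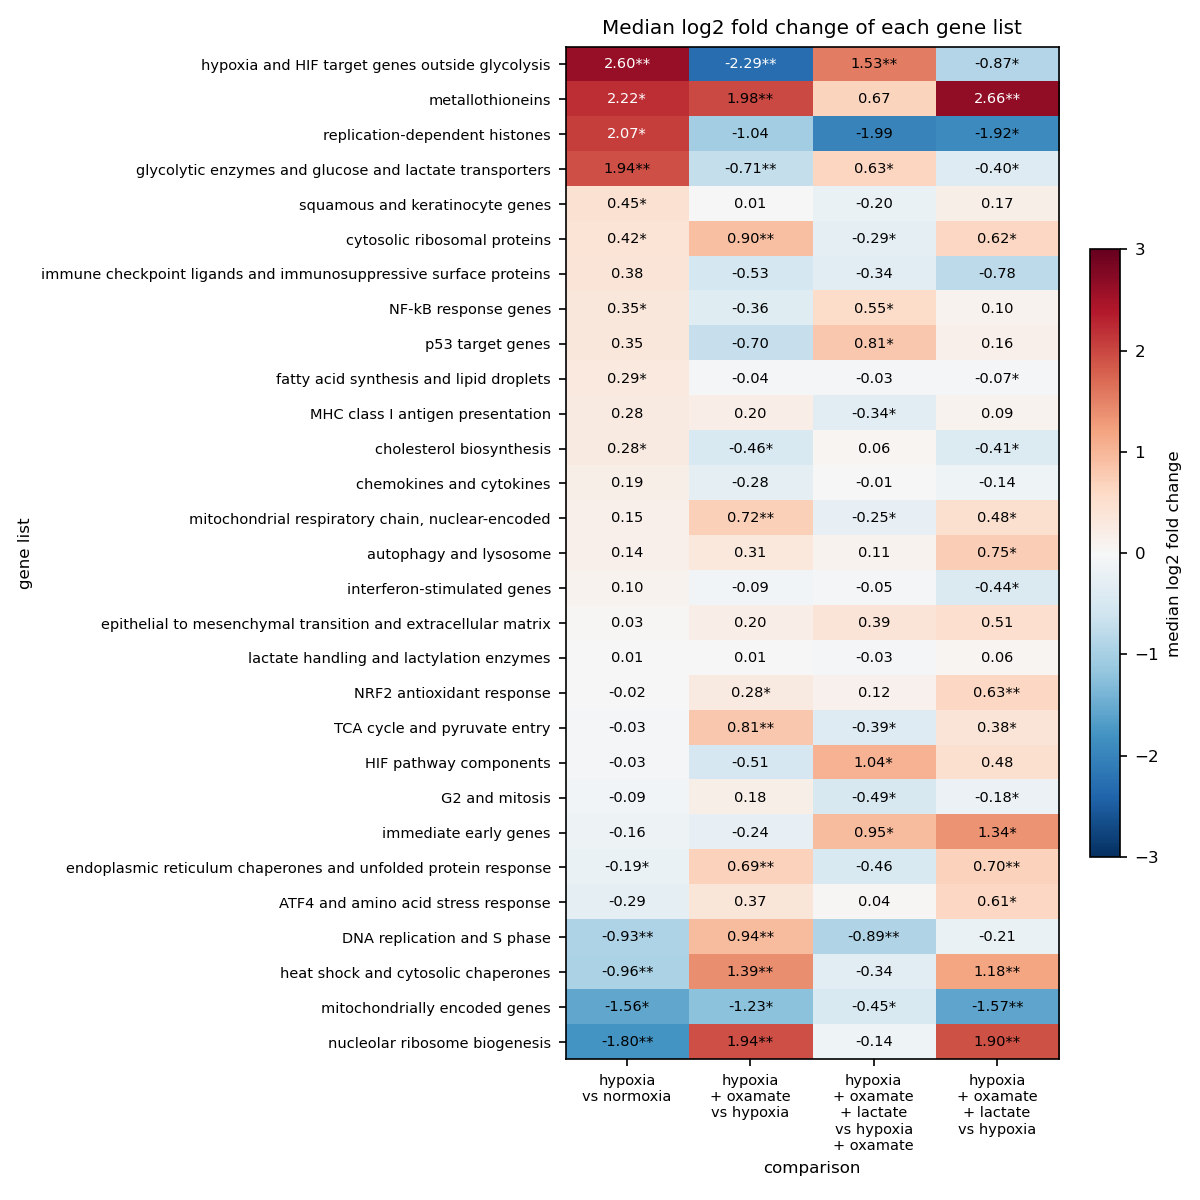
Median log2 fold change of the tested members of each gene list (rows) in the 4 comparisons (columns), on a colour scale from blue for lower to red for higher, with an asterisk for a camera adjusted p under 0.05 and 2 where this also holds with an estimated correlation. The hypoxia and HIF target list runs from 2.60 in hypoxia to -2.29 with oxamate and 1.53 on adding lactate, with medians of -1.80, 1.94 and -0.14 for nucleolar ribosome biogenesis.

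The effect of hypoxia and that of oxamate ran in opposite directions for most called genes. Of the 5702 genes higher in hypoxia, 4153 (72.8%) were lower with oxamate and 922 (16.2%) were higher again. Of the 5727 genes lower in hypoxia, 3681 (64.3%) were higher with oxamate and 1244 (21.7%) were lower again. Independent lists of these sizes would share 2553 and 2047 genes, a reference that ignores the shared hypoxia group. Simulated groups without any effect shared 0.4 on average, but they yield almost no calls. That count therefore cannot show how far the shared hypoxia libraries raise the overlap of real effects. The covariance of the log2 fold changes over all tested genes was -1.30, against -0.051 in the simulation, a difference of -1.25. The simulation holds no effects, so its covariance is small and the difference alone does not show a reversal. The Pearson correlation was -0.644, and -0.498 in the simulation. Opposite signs were held by 71.3% of all tested genes, and by 66.4% in the simulation. Both comparisons use the hypoxia libraries, which pushes the signs of the effects apart, in noise and in real differences alike. On a log2 CPM scale the covariance was -0.999 with both hypoxia libraries in both effects, and -0.965 and -0.962 with a different hypoxia library in each effect, a split chosen after the overlap was seen. On that scale 70.4% of genes held opposite signs in each split, against 71.4% with both libraries in both effects. A split takes out the noise of the shared libraries, not a real deviation of the hypoxia group, which enters both effects.

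The third comparison asked what adding lactate to oxamate changed in hypoxia. Hypoxia-response genes rose again and genes of DNA replication fell. VEGFA rose from 16.2 ± 1.51 to 78.9 ± 2.78 CPM (2.29 ± 0.062, n = 2 per group), and SLC2A1 from 556 ± 5.46 to 1699 ± 79.5 CPM (1.61 ± 0.032). CA9 rose by 1.21 ± 0.099, to 18.5 ± 1.88 CPM. LDHA rose by 0.76 ± 0.026 and LDHB fell (-0.42 ± 0.031). The genes of the HIF-1 complex rose, HIF1A by 0.77 ± 0.036, ARNT by 1.49 ± 0.070 and EP300 by 1.26 ± 0.070. CD274 was called higher, from 42.2 ± 2.63 to 49.4 ± 2.10 CPM (0.23 ± 0.061, adjusted p = 0.00252). That call ended without oxamate replicate 1 (0.06), with upper quartile normalization (0.04), with the stricter count filter (0.11) and with DESeq2 (0.17).

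Of 38 hypoxia and HIF target genes, 32 rose with lactate and 2 fell (median 1.53, adjusted p = 0.0143 with an estimated correlation), including the histone demethylase gene KDM3A (2.68 ± 0.035) and DDIT4 (2.71 ± 0.034). Of 44 DNA replication and S phase genes, 43 fell and none rose (median -0.89, adjusted p = 0.0399 with an estimated correlation), including CDC6 (-1.94 ± 0.047) and MCM10 (-1.97 ± 0.051). Of 23 genes of glycolysis and glucose and lactate transport, 19 rose and 4 fell (median 0.63, adjusted p = 0.107 with an estimated correlation), including HK2 (3.11 ± 0.028) and SLC2A3 (3.07 ± 0.035). Of 39 genes of G2 and mitosis, 33 fell and 5 rose (adjusted p = 0.157 with an estimated correlation), including AURKB (-1.31 ± 0.047) and NUSAP1 (-1.05 ± 0.038). All 51 cytosolic ribosomal protein genes fell, with a median of -0.29 (adjusted p = 0.174 with an estimated correlation), including RPLP0 (-0.36 ± 0.025) and RPL27 (-0.42 ± 0.030). Immediate early genes rose in 17 of 25 cases and fell in 3 (adjusted p = 0.248 with an estimated correlation), including the transcription factor genes KLF10 (3.19 ± 0.063) and JUNB (3.13 ± 0.074). JUNB shares 14.2% of its exon bases with HOOK2, which was at 30.7 and 32.3 CPM with oxamate, above JUNB.

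Another 7 lists were called, none of which held with an estimated correlation. TCA cycle genes fell in 21 of 25 cases, with none higher (adjusted p = 0.0801 with an estimated correlation). Nuclear respiratory chain genes fell in 44 of 58 cases and rose in 7 (adjusted p = 0.174 with an estimated correlation), and mitochondrial genes fell in 10 of 13 and rose in 2 (adjusted p = 0.294 with an estimated correlation). MHC class I genes, several of which share reads with similar copies, fell in 15 of 20 cases and rose in 2 (median -0.34, adjusted p = 0.157 with an estimated correlation). HIF pathway components rose in 10 of 14 cases and fell in 3, p53 target genes rose in 16 of 25 and fell in 6 (median 0.81, or 0.82 with TP53INP1 at its bound), and NF-kB response genes rose in 12 of 19 and fell in 3. For each of these 3 lists the adjusted p was 0.157 with an estimated correlation. Nucleolar ribosome biogenesis, with 8 of 32 higher and 18 lower, and heat shock genes, with 6 of 19 higher and 10 lower, were not called (adjusted p = 0.339 and 0.0638). The immune checkpoint list, with 3 of 16 higher and 10 lower (4 and 10 adjusted over the list alone), was not called (adjusted p = 0.0941).

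ARRDC3, encoding an arrestin-domain protein, rose from 11.1 ± 0.0456 to 319 ± 11.1 CPM (4.84 ± 0.053). TCP11L2 rose by 4.61 ± 0.244 and APOLD1 by 4.11 ± 0.208, although APOLD1 shares 25.4% of its exon bases with the more abundant DDX47. GNRH1 had 204 counts with lactate against 6 without, a ratio of 38.9 (interval 17.6 to 107), and the noncoding RENO1 had 66 against 4, a ratio of 18.9 (interval 7.03 to 71.3). Among those open to the naming rule, the largest decreases were in BHLHE40-AS1 (-4.19 ± 0.337), the histone gene H3C10 (-2.39 ± 0.221), the arginine methyltransferase gene PRMT6 (-2.27 ± 0.140), NDUFC2-KCTD14 (-2.21 ± 0.375) and LNP1 (-2.20 ± 0.365). NDUFC2-KCTD14 is a read-through of neighbouring genes and LNP1 overlaps TOMM70, so both are uncertain, like the antisense BHLHE40-AS1. edgeR called 5160 genes higher and 4927 lower, of which 2289 and 699 differed at least 2-fold. Of 17 replication-dependent histone genes, 1 was higher and 12 lower (1 and 13 adjusted over the list alone), and the list was not called (median -1.99, or -1.81 with H2BC17 at its bound, adjusted p = 0.221). The mitochondrial share was 2.14% and 2.09% with lactate, that of mitochondrial ribosomal RNA 1.06% and 1.00%, and that of lincRNA and antisense genes 0.545% and 0.515%. Upper quartile normalization changed the split of calls from 51.2% to 39.6% higher. That setting shifted the median of all genes by 0.105 in hypoxia against normoxia, by -0.19 on adding lactate to oxamate and by -0.26 for lactate with oxamate against hypoxia. On adding lactate, lower genes also outnumbered higher ones with RLE size factors (5383 against 4858), the stricter filter (5554 against 4244) and DESeq2 (4669 against 4350). Higher genes remained more numerous without a low-count filter (5223 against 4776) and in a fit of the 2 groups alone (4923 against 4636).

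Of the 6965 genes lower with oxamate, 3362 (48.3%) were higher on adding lactate and 1089 (15.6%) lower again. Of the 5560 genes higher with oxamate, 3145 (56.6%) were lower on adding lactate and 1185 (21.3%) higher again. Independent lists would share 2311 and 1761, a reference that ignores the shared oxamate group. Simulated groups without effect shared 0.45, a count that is again near 0 because they yield almost no calls. The covariance was -0.809, against -0.0541 in the simulation, a difference of -0.755 that again does not show a reversal by itself. The Pearson correlation was -0.457, and -0.498 in the simulation. Opposite signs were held by 65.9% of all tested genes, and by 66.7% in the simulation. Sharing the oxamate group pushes signs apart, in noise and in real differences alike. Over all genes, correlation and signs thus show no reversal by lactate beyond that of the simulation. With a different oxamate library in each effect the covariance on the log2 CPM scale was -0.478 and -0.475, against -0.531 with both in both. On that scale 65.1% of genes held opposite signs in each split, against 65.8% with both in both. The split again takes out only the noise of the shared libraries. A total of 1936 genes were higher in hypoxia, lower with oxamate and higher with lactate. Of these, 341 did not differ from hypoxia without drug, 1112 stayed below it and 483 were above it. By adjusted p, GPRC5A, SLC2A3, DDIT4 and CCNG2 led this set. GPRC5A, encoding an orphan receptor, changed by 3.46 ± 0.029, -2.43 ± 0.027 and 2.45 ± 0.027 in the 3 steps, and the cyclin gene CCNG2 by 4.64 ± 0.051, -2.51 ± 0.041 and 2.81 ± 0.041. The opposite pattern held for 2110 genes, of which 368 did not differ from hypoxia, 1487 stayed above it and 255 were below it, with MCM10, TMPO and MCM3 among those of smallest adjusted p. The helicase subunit gene MCM3 changed by -1.20 ± 0.029, 1.27 ± 0.029 and -1.08 ± 0.030, and TMPO, a nuclear lamina gene, by -1.15 ± 0.032, 1.12 ± 0.033 and -1.45 ± 0.034.

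**Figure D3:**
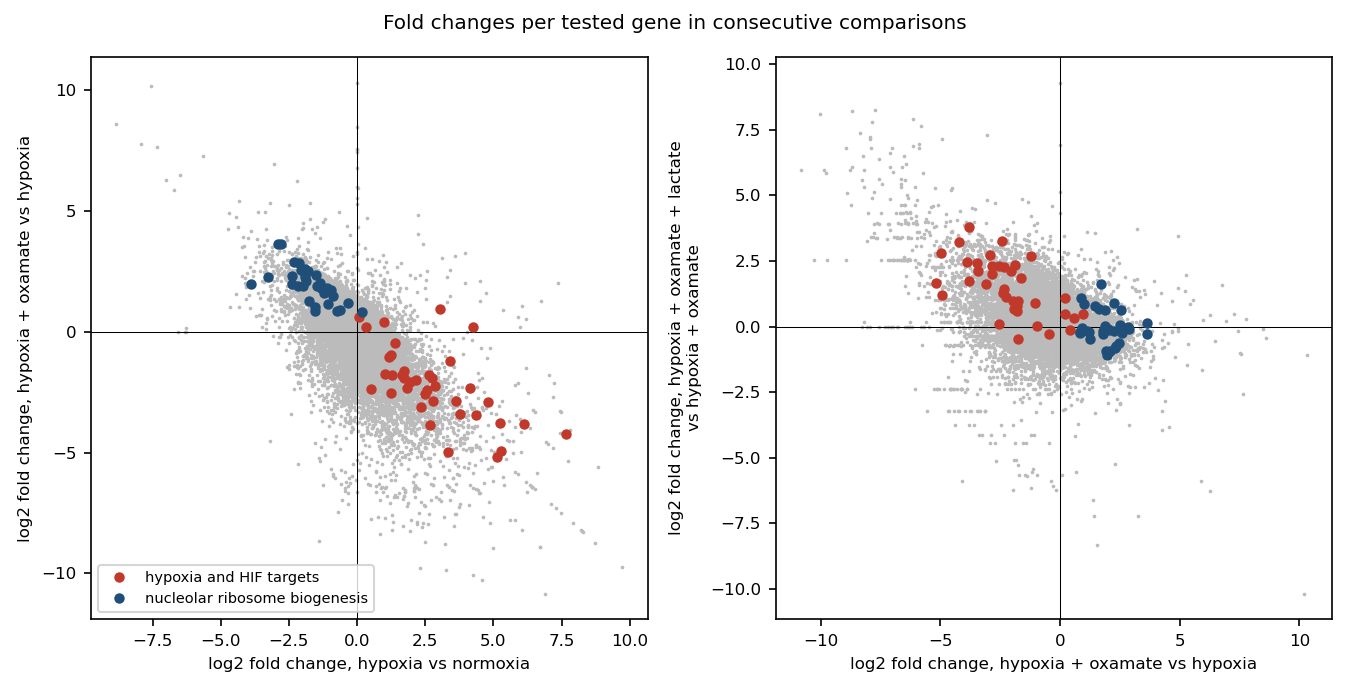
Log2 fold change of each of the 15554 tested genes in hypoxia (left, horizontal axis) and with oxamate (left, vertical axis), and with oxamate (right, horizontal axis) and on adding lactate (right, vertical axis), with covariances over all genes of -1.30 and -0.809. Red points are hypoxia and HIF target genes outside glycolysis and blue points nucleolar ribosome biogenesis genes, and stripes of grey points are genes without counts in a group.

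The last comparison asked what remained of the oxamate difference once lactate was present. VEGFA did not differ detectably from hypoxia alone (-0.05 ± 0.049, adjusted p = 0.324, n = 2 per group), although it passed as lower with upper quartile normalization (-0.31) and with the stricter count filter (-0.14). CA9 stayed lower by a log2 fold change of -3.72 ± 0.063, and LDHA stayed lower at -0.35 ± 0.025. SLC2A1 (1.32 ± 0.031), HIF1A (1.19 ± 0.036), LDHB (0.91 ± 0.032), EP300 (0.68 ± 0.065) and ARNT (0.40 ± 0.062) were higher than in hypoxia alone. CD274 was higher by 1.79 ± 0.069 (adjusted p = 3.55e-16).

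All 32 nucleolar ribosome biogenesis genes were higher than in hypoxia alone (median 1.90), as were 16 of 19 heat shock genes, with 2 lower (median 1.18), all 5 metallothionein genes (2.66), 18 of 23 endoplasmic reticulum chaperone genes, with 3 lower (0.70), and 16 of 23 NRF2 antioxidant genes, with 1 lower (0.63). All 13 mitochondrial genes were lower (median -1.57). These 6 lists were called with the preset and with an estimated correlation, where their adjusted p lay between 0.00632 and 0.0487. Of 38 hypoxia and HIF target genes, 25 were lower and 8 higher (median -0.87, adjusted p = 0.0621 with an estimated correlation), and of 23 glycolysis genes, 16 were lower and 6 higher (median -0.40, adjusted p = 0.126 with an estimated correlation). Immediate early genes were higher in 19 of 25 cases and lower in 4 (adjusted p = 0.158 with an estimated correlation), and histone genes lower in 13 of 17 and higher in 1 (adjusted p = 0.158 with an estimated correlation). Cytosolic ribosomal protein genes were higher in 50 of 51 cases and lower in 1 (adjusted p = 0.0928 with an estimated correlation), and nuclear respiratory chain genes in 49 of 58, with 4 lower (adjusted p = 0.0753 with an estimated correlation). ATF4 and amino acid stress genes were higher in 22 of 35 cases and lower in 9 (adjusted p = 0.0753 with an estimated correlation), and genes of autophagy and lysosome higher in 21 of 28 and lower in 6 (adjusted p = 0.079 with an estimated correlation). The immune checkpoint list, with 5 of 16 higher and 10 lower, was not called (adjusted p = 0.0715).

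Another 5 lists lost their call with an estimated correlation. TCA cycle genes, with 14 of 25 higher and 8 lower, had an adjusted p = 0.122 with an estimated correlation, and also lost the call with upper quartile normalization (median 0.12), with the stricter count filter (0.29) and in a fit of the 2 groups alone (0.37). Genes of G2 and mitosis, with 24 of 39 lower and 8 higher, had an adjusted p = 0.189 with an estimated correlation. Cholesterol biosynthesis genes were lower in 12 of 22 cases and higher in 5, and genes of fatty acid synthesis lower in 11 of 24 and higher in 9, both at an adjusted p = 0.0753 with an estimated correlation. Interferon-stimulated genes were lower in 16 of 30 cases and higher in 7 (adjusted p = 0.118 with an estimated correlation). Without a low-count filter the fatty acid and interferon lists also lost their call (median -0.09 and -0.46). The lists of lactate handling and lactylation enzymes, chemokines and cytokines, and epithelial to mesenchymal transition were called in none of the 4 comparisons, with smallest camera adjusted p of 0.309, 0.785 and 0.463. Median, mean and test had the same sign in each called list, but differed in several lists that were not called. Among these were ATF4 genes with oxamate (median 0.37, mean -0.06), immediate early genes with oxamate (median -0.24, test toward higher), endoplasmic reticulum chaperones on adding lactate (median -0.46, mean 0.12) and p53 targets in hypoxia (median 0.35, mean -0.04). edgeR called 5981 genes higher and 6246 lower, of which 2286 and 3552 differed at least 2-fold. Upper quartile normalization changed the split from 48.9% to 37.8% higher.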

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

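All alternatives were chosen before the data were examined. For the counts of genes and lists, 295 alternative values stayed within 1.5 times the reported count and 25 did not. No named gene or called list reversed. Against a fold change of 1.5, 2885 genes were higher and 2841 lower in hypoxia, 3291 higher with oxamate, 2710 higher and 1108 lower on adding lactate, and 3374 higher and 4024 lower for lactate with oxamate against hypoxia. The overlaps of opposite direction then held 2153, 1559, 1665 and 468 genes, since that test asks for a larger change. With an estimated correlation, 2 lists were higher and 3 lower in hypoxia, 2 lower with oxamate, 1 higher and 1 lower on adding lactate, and 5 higher and 1 lower against hypoxia. With fry, which does not compare a list with other genes, the counts were 18 and 9, 14 and 13, 15 and 13, and 19 higher in the last comparison. The cause of other changes was not tested.

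Differences between replicates 1 and 2 were almost uncorrelated across groups (from -0.0502 to 0.0118). This cannot exclude a pairing of libraries, because genes with few counts add noise to the differences. A replicate block left 5620 higher and 5681 lower genes in hypoxia, 5527 and 6936 with oxamate, 5111 and 4870 on adding lactate, and 5961 and 6185 against hypoxia. DESeq2 called 9922 of 11429, 11267 of 12525, 8917 of 10087 and 11013 of 12227 of the same genes, none in the opposite direction. Leaving out each library in turn kept every count within 1.5 times, with the lone library assumed to vary like the other groups. Calls of lists were kept in 888 alternative values and ended in 51, of which 36 came from the estimated correlation. Results of named genes were kept in 1865 alternative values, calls ended in 19, of which 14 came from the test against 1.5-fold, and 4 were gained. Depth limits genes with few counts, whose ratios carry wide counting intervals.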

Other observations

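The test of genomic DNA and the test of recovery with lactate were set before their results were seen, and the other 6 tests below were chosen only after the result was seen, as were the genes of the next 2 paragraphs.

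The keratin and matrix metalloproteinase genes given here are single genes, and the squamous and keratinocyte list went both ways with oxamate (12 of 25 higher and 11 lower) and on adding lactate (9 higher and 10 lower), and was called in neither. KRT5, which encodes a basal keratin, changed by -0.79 ± 0.025 in hypoxia, by 1.84 ± 0.025 with oxamate and by -0.66 ± 0.025 on adding lactate (n = 2 per group). KRT6A changed by -1.33 ± 0.059, 2.39 ± 0.055 and -0.76 ± 0.048 in the same steps. KRT15 changed by 3.50 ± 0.033, -2.99 ± 0.032 and 0.28 ± 0.031. The collagenase gene MMP13 changed by -2.27 ± 0.161 in hypoxia, by 2.54 ± 0.159 with oxamate and by a further 0.57 ± 0.119 with lactate. MMP1 changed by -1.82 ± 0.268 and 2.58 ± 0.256, and its further difference with lactate did not pass (0.24 ± 0.203).

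The stress genes given here are single genes too, and on adding lactate the lists of NRF2 antioxidant genes (11 of 23 higher and 8 lower) and of ATF4 and amino acid stress genes (16 of 35 higher and 15 lower) were not called. GCLC, encoding a subunit of the enzyme that starts glutathione synthesis, changed by -1.21 ± 0.043 in hypoxia, 1.39 ± 0.043 with oxamate and 1.70 ± 0.037 on adding lactate. SLC7A11, encoding a cystine transporter, changed by -1.75 ± 0.149 in hypoxia, did not pass with oxamate (-0.06 ± 0.183) and rose by 2.43 ± 0.151 on adding lactate. GDF15, encoding a stress cytokine, rose in each step, by 0.56 ± 0.208, 1.90 ± 0.150 and 2.84 ± 0.097. DDIT3, encoding the stress transcription factor CHOP, changed by 0.80 ± 0.107, -1.29 ± 0.117 and 3.25 ± 0.102. MYC changed by -0.96 ± 0.072, 1.71 ± 0.067 and 1.60 ± 0.051.

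Of 1688 lincRNA and antisense genes, 947 were lower with oxamate and 177 higher, with a median log2 fold change of -1.25 against -0.05 for protein-coding genes, after 689 higher and 251 lower in hypoxia (median 0.56), while on adding lactate 269 were higher and 262 lower (median -0.05) and the median against hypoxia was -1.25. The median was -1.17 under RLE size factors and -1.32 under upper quartile normalization, against 0.03 and -0.12 for protein-coding genes. These settings shifted the median of all genes by only 0.082 and -0.068, so they cannot exclude a larger error of scaling. A scaling factor moves both kinds of gene alike, however, and leaves the gap between them. Low abundance left a difference, since protein-coding genes matched on abundance had a median of -0.76, a difference of -0.49 (bootstrap 95% interval -0.64 to -0.37), although they were lower too. The bootstrap resampled gene pairs measured in the same libraries, so its interval does not cover the spread between libraries. Genomic DNA is argued against by olfactory receptor genes, whose density in the hypoxia libraries reached 2.33% of the lost noncoding density. An effect of oxamate on these RNAs and a difference in RNA quality or capture both stay open, since mitochondrial ribosomal RNA went from 1.34% and 1.31% to 0.964% and 0.966% in the same libraries, histone genes had a median of -1.04 (9 of 17 lower and 3 higher, not called), and strandedness is not stated.

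Mitochondrial transcripts fell unequally in hypoxia. Nuclear copies did not take up the reads, since their sum changed by -2.92% of the CPM lost by 7 mitochondrial genes, where a gain was needed. Of the 13 genes, 4 lay above -0.2 by over 2 standard errors and 7 below -1. Mitochondrial ribosomal RNA did not fall, since its share in the lower hypoxia library was 2.12 times that in the higher normoxia library. In poly(A)-selected RNA that share also depends on capture. Replication-dependent histone genes were higher in hypoxia too (13 of 17, none lower, median 2.07, not called with an estimated correlation). The ribosomal share therefore cannot decide on a general loss of mitochondrial mRNA. MT-ND6 rose by 0.42 ± 0.033, but it is a single gene and is uncertain because strand was not stated. Differences in polyadenylation, RNA stability or capture between these transcripts may contribute and were not tested.

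CD274 was lower in hypoxia and higher with oxamate. The decrease was -0.38 or lower under RLE size factors and upper quartile normalization. These settings shifted the median of all genes by only 0.0014 and 0.105, so they cannot exclude a larger error of scaling. A swap of normoxia and hypoxia labels is argued against by CA9, NDRG1 and ANKRD37, the smallest of whose ratios between the lower hypoxia and the higher normoxia library was 33.1. That hypoxia and oxamate act in opposite directions on CD274 mRNA may be held as a hypothesis, and PD-L1 protein was not measured here.

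It was also asked whether genes of the hypoxia and HIF target list and of the glycolysis list, taken as one set, recovered more with lactate than other genes of like oxamate response. Among genes higher in hypoxia and lower with oxamate, 51 genes of the 2 lists recovered a median of 56.1% of the oxamate change, against 39.9% for genes matched on both fold changes and abundance. The difference of 16.2 points did not pass (permutation p = 0.056, two-sided, 100000 resamples), so these data do not settle it. The 4102 other genes, unmatched, had a median of 24.8%.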
